A study of Homo sapiens with 12 samples.

How the data were processed

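Total RNA from 2 prostate cancer cell lines was measured on 12 single-colour Affymetrix arrays, with target prepared by the WT PLUS kit and labelled with biotin, per the labels' protocols. The authors deposited log2 values, 1 per transcript cluster and array, and the submitters' processing notes name Affymetrix Expression Console, RMA and limma without versions. RMA corrects background, normalizes the arrays to a common distribution and summarises the probes of a transcript. The deposited log2 values ran from 1.66 to 18.6, which is wide for RMA alone. A further step that widens contrast cannot be excluded from the values, so every fold change given here is on the deposited scale and can be larger than the change in RNA. The summarisation options and annotation build are not given in the sources used here.

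The table held 24351 rows, of which 94 were background or spike-in controls. A gene symbol was taken from the platform's annotation, with Entrez identifiers matched to the RefSeq gene table for all 17709 rows that had 1 symbol, and no symbol needed an update. No row had several symbols, and 6642 rows, controls included, had none here. Where several rows shared a symbol, as for 20 genes, the brightest over all arrays was kept, which left 17687 genes. RHOU was the only gene named below with a second row. Some receptor and glucocorticoid target genes of the fixed lists had no named row and are not analysed here.

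Each array's group and replicate number came from its title. The 4 groups are called Abi_Ctrl, Abi_Dex, Enza_Ctrl and Enza_Dex, with 3 arrays each. The labels call the experiments triplicates without saying whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical. No pair of arrays was identical, with a highest Pearson r of 0.996 between any pair. The number of arrays limits the precision, since these files hold no read depth. Array quality was read from the spike-in, hybridization and background control rows and from the correlation of each array with the others.

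Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, statmod 1.5.0). All 12 arrays entered with 4 group means, no filter on dim genes and no replicate block. The 4 comparisons were dexamethasone against DMSO in each line, the difference between those responses (Enza minus Abi), and Enza_Ctrl against Abi_Ctrl. Comparisons that share DMSO arrays are not independent. Enza_Ctrl enters the comparison of the untreated lines and the response of LNCaPabl-Enza with opposite signs. The difference between the responses holds the DMSO arrays of both lines with signs opposite to the comparison of the untreated lines. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Because a single array, Enza_Ctrl replicate 2, stood apart, each count is given with all 12 arrays and again without it. Leaving out each array in turn was planned. The choice to print this omission beside every count, and the alternatives that combine it with a block or with fewer groups, were made after seeing the data.

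The 31 gene lists were fixed before the data were examined. They covered steroid receptor targets, steroid and lipid metabolism, the cell cycle, stress and signalling responses, and markers of epithelial, neuroendocrine, mesenchymal, fibroblast, immune and endothelial cells. Each list was tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the 31 lists of a comparison. Genes were named by a rule also fixed before the data were examined. It took up to 10 called genes with the highest and up to 10 with the lowest difference whose groups did not overlap, called members of each list (up to 4) or the member with the smallest p in the comparisons with dexamethasone, and NR3C1, TSC22D3, KLK3 and MKI67 in every comparison. The rule was applied to both sets of arrays. Y-linked genes it selected count in the totals and are not named. Members of lists that are named because they passed when adjusted over the list alone, and members of lists named for the untreated lines, were chosen after their values were seen.

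The script was tested on simulated data with the real gene means and spreads, in which 200 genes were changed. For dexamethasone in LNCaPabl-Abi, log2 changes of 1, 2 and 4 were recovered in 11.9%, 65.7% and 95.5% of changed genes with 12 arrays, and in 62.7%, 97.0% and 100.0% without Enza_Ctrl replicate 2. For LNCaPabl-Enza, the shares were 13.4%, 56.7% and 100.0% with 12 arrays and 43.3%, 95.5% and 100.0% without that array. For the difference between the responses, a log2 change of 1 was recovered in 0% and 17.9% of changed genes, and a change of 2 in 31.3% and 76.1%. The simulated arrays varied independently, with the same spread of a gene in every group, and 200 changed genes ease the adjustment. The shares can therefore be too high where real replicates are uneven. SGK1 in LNCaPabl-Enza, at 4.43 without Enza_Ctrl replicate 2, was not called (limma adjusted p = 0.269). Alternatives tried were quantile normalization anew, centring on the median, leaving out the dimmest 33.3% of genes, eBayes with trend and robust settings, only the groups compared, the replicate number as a block, array weights, the mean of a gene's rows, every row tested alone, and leaving out each array.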

Results

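Gene expression was profiled in LNCaPabl-Abi and LNCaPabl-Enza, 2 sublines named after LNCaP, an established human prostate cancer cell line. The labels do not spell out what Abi and Enza stand for. Each line received the solvent DMSO or 100 nM dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, for 24 h. The 4 groups held 3 arrays each, and levels are given as deposited log2 values. The series asks how glucocorticoid receptor signalling changes expression in these lines.

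Enza_Ctrl replicate 2 stood apart from the other 11 arrays. Its median Pearson r with the others was 0.855, while each of the other 11 had a median r between 0.986 and 0.990. The 4 poly-A spike-ins, which are added to the RNA before labelling, averaged 3.46 on this array and 7.07 to 8.10 on the others. The 4 hybridization controls averaged 13.94 against 10.49 to 11.43, and the background probes 4.74 against 2.77 to 2.92. With this array the median residual SD of a gene was 0.43 on the log2 scale, and without it 0.26.

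**Figure D1:**
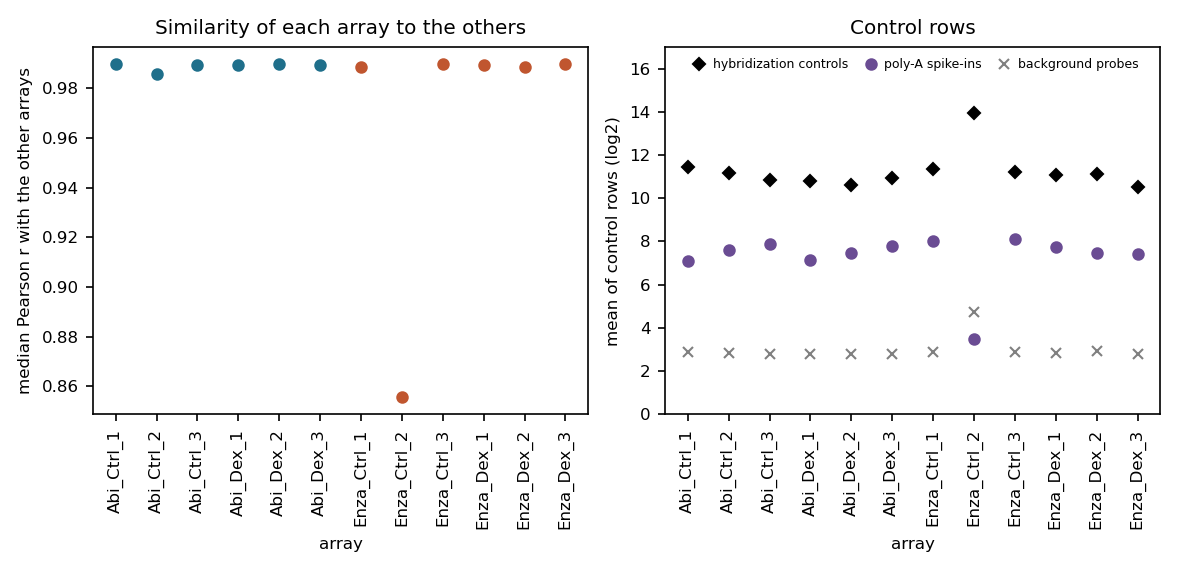
Left, median Pearson r of each of the 12 arrays with the other arrays (y axis from 0.85, not from 0), coloured by line. Right, mean log2 value of the hybridization controls (diamonds), poly-A spike-ins (circles) and background probes (crosses) of each array, where Enza_Ctrl replicate 2 has the lowest spike-ins (3.46) and the highest hybridization controls (13.94).

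NR3C1, which encodes the glucocorticoid receptor, was measured at 11.31 ± 0.18 (SD, n = 3) in Abi_Ctrl and at 8.11 ± 2.01 (SD, n = 3) in Enza_Ctrl. The difference of -3.20 ± 0.88 (SE) had an adjusted p of 0.261 over all genes and 0.0265 when adjusted over the list alone, that of 7 measured steroid hormone receptors. The Enza arrays were uneven: replicate 3 had 10.37 with DMSO and 9.03 with dexamethasone, while the remaining Enza arrays lay between 6.38 and 7.43. After dexamethasone, NR3C1 was at 9.86 ± 0.38 (SD, n = 3) in Abi_Dex, a difference of -1.45 ± 0.88 (SE) with an adjusted p of 1.00. The corresponding difference in LNCaPabl-Enza was -0.73 ± 0.88 (SE), with an adjusted p of 0.638, or -1.06 ± 0.84 without Enza_Ctrl replicate 2. The SE pools the spread of all 4 groups, so the uneven Enza arrays also widen it for LNCaPabl-Abi. There the groups did not overlap, with 9.44 to 10.16 after dexamethasone and 11.14 to 11.49 with DMSO. Of all genes, 12.3% had no overlap between these groups, so a change of NR3C1 in LNCaPabl-Abi was neither called nor excluded.

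In LNCaPabl-Abi, dexamethasone raised SGK1, PGC, KLK4, SCNN1G and TMPRSS2. SGK1, a kinase induced by glucocorticoids that promotes epithelial sodium uptake, went from 6.18 ± 0.35 to 13.57 ± 0.27 (SD, n = 3), a log2 difference of 7.39 ± 0.73 (SE) and 168-fold on the deposited scale. KLK4, a secreted prostate protease induced by androgens, rose by 4.73 ± 0.50 (26.5-fold). PGC, the precursor of the gastric protease pepsin C, rose by 4.57 ± 0.55 (23.7-fold), and SCNN1G, the gamma subunit of the epithelial sodium channel, by 3.15 ± 0.29 (8.88-fold). TMPRSS2, an androgen-induced serine protease of prostate epithelium, rose by 2.19 ± 0.27 (4.55-fold).

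These were the 5 genes called by limma with all 12 arrays (adjusted p from 0.00461 to 0.0167), with 0 genes called lower. Without Enza_Ctrl replicate 2 the count was 25, again with 0 lower, and it included all 5. Each of the 25 was higher in every Abi_Dex array than in every Abi_Ctrl array, an order that chance gives 10% of genes in 1 direction or the other and that 12.3% of all genes showed. The added genes with the highest differences were FAXDC2 at 3.87 ± 0.57 (SE), SPSB1 at 3.41 ± 0.42, HTR3A at 2.85 ± 0.31, TUBA3D at 2.77 ± 0.36 and MYBPC1 at 2.70 ± 0.44, with adjusted p from 0.000393 to 0.0163. RHOU, which encodes a small GTPase and is induced by androgens, was at 1.89 ± 0.30 (adjusted p = 0.0163), and DUSP4, a phosphatase that limits MAP kinase signalling, at 1.42 ± 0.26 (adjusted p = 0.0449). The count fell to 0 without Abi_Ctrl replicate 2, where SGK1 had an adjusted p of 0.0643, and the leave-out counts of all arrays ran from 0 to 25.

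**Figure D2:**
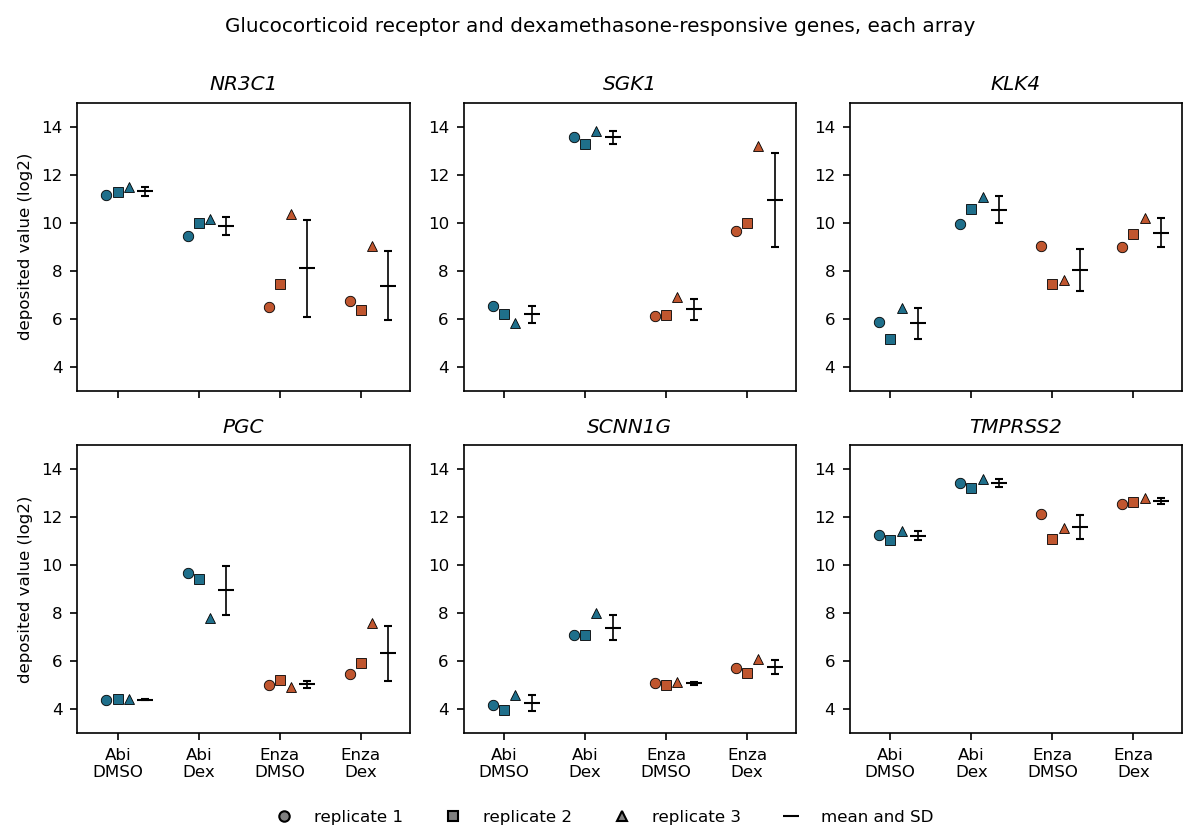
Deposited log2 value of 6 genes on each array (points, shaped by replicate), with the mean and SD of each group of 3 beside them. SGK1 sits between 13.29 and 13.83 in Abi_Dex, and in Enza_Dex at 9.66, 9.99 and 13.20, with the highest value in replicate 3, the replicate with the highest NR3C1 among the Enza arrays.

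Of 28 measured glucocorticoid-induced genes, 22 had a positive difference in LNCaPabl-Abi, with a median log2 difference of 0.49. SGK1 was the only member called over all genes with either set of arrays. SGK1 and KLF15 passed with 12 arrays when adjusted over the list alone (KLF15 0.91 ± 0.24), and 9 members without Enza_Ctrl replicate 2. Those 9 included KLF9 at 0.98 ± 0.19 (SE), ERRFI1 at 1.08 ± 0.27 and TSC22D3, the anti-inflammatory protein GILZ, at 1.50 ± 0.45. The list was higher by camera (adjusted p = 2.98e-12), and stayed so with an estimated correlation (adjusted p = 0.00104).

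The epithelial sodium transport list was also higher in LNCaPabl-Abi after dexamethasone (camera adjusted p = 3.06e-10; adjusted p = 0.00782 with an estimated correlation). SCNN1G and SGK1 were called among its 11 measured members. When adjusted over the list alone, 2 passed with 12 arrays and 5 without Enza_Ctrl replicate 2, which added the channel subunit SCNN1B at 1.05 ± 0.26 (SE), the ubiquitin ligase NEDD4L at 0.64 ± 0.18 and TSC22D3. SGK1 and TSC22D3 are members of this list and of the glucocorticoid list, so the 2 results share these genes.

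Androgen-induced genes were higher as a list (camera adjusted p = 9.68e-09; adjusted p = 0.0439 with an estimated correlation, and 0.202 without Enza_Ctrl replicate 2). Of 23 measured members, 16 had a positive difference, and KLK4 and TMPRSS2 were called with 12 arrays. Adjusted over the list alone, 4 passed, namely those 2, RHOU and the kallikrein KLK2 at 1.76 ± 0.43 (SE), and 5 passed without that array. The fifth was KLK3, which encodes prostate-specific antigen and was at 1.76 ± 0.42 without the array (adjusted p = 0.247 over all genes). The measured members of this list and of the glucocorticoid list have no gene in common.

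Cell division genes were lower in LNCaPabl-Abi after dexamethasone as a list (camera adjusted p = 5.43e-15), but with an estimated correlation of 0.58 between its genes the adjusted p was 0.296. All 30 measured members had a negative difference, with a median of -0.50. No member was called over all genes. Adjusted over the list alone, 0 passed with 12 arrays and 12 without Enza_Ctrl replicate 2, among them the kinetochore gene NDC80 at -0.85 ± 0.23 (SE), the cyclin CCNA2 at -0.76 ± 0.23 and the motor protein gene KIF23 at -0.71 ± 0.23. MKI67, the Ki-67 proliferation marker, was at -0.53 ± 0.39 (SE) with an adjusted p of 1.00.

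DNA replication genes had a negative difference for 28 of 30 members in LNCaPabl-Abi (median -0.34, camera adjusted p = 6.08e-05; adjusted p = 0.679 with an estimated correlation). This call ended without Abi_Ctrl replicate 3 (adjusted p = 0.272). The unfolded protein response list had 20 of 20 positive differences (median 0.26, camera adjusted p = 0.000426; adjusted p = 0.467 with an estimated correlation). Luminal epithelial markers had 11 of 13 positive differences (camera adjusted p = 0.000544; adjusted p = 0.130 with an estimated correlation), and fatty acid synthesis genes 13 of 16 (camera adjusted p = 0.00262; adjusted p = 0.467 with an estimated correlation). Without Abi_Dex replicate 1 the unfolded protein response (adjusted p = 0.145) and fatty acid synthesis (adjusted p = 0.0572) calls ended. The MAPK feedback and immediate early list had 18 of 23 positive differences (camera adjusted p = 0.0363; adjusted p = 0.211 with an estimated correlation), and its call ended without Enza_Ctrl replicate 2 (adjusted p = 0.0826), Abi_Ctrl replicate 2 (0.247), Abi_Ctrl replicate 3 (0.09998) or Abi_Dex replicate 1 (0.154). None of the lists of androgen-repressed, basal, neuroendocrine, mesenchymal, fibroblast, immune or endothelial genes was called by camera in this comparison with 12 arrays.

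In LNCaPabl-Enza, SGK1 was at 6.40 ± 0.43 with DMSO and at 10.95 ± 1.95 with dexamethasone (SD, n = 3). Its difference of 4.55 ± 0.73 (SE) did not pass over all genes (adjusted p = 0.523). TMPRSS2 was at 1.08 ± 0.27 (SE), KLK4 at 1.55 ± 0.50, PGC at 1.29 ± 0.55 and SCNN1G at 0.69 ± 0.29, each short of the threshold. TSC22D3 was at 0.55 ± 0.53 (adjusted p = 0.564; 0.39 ± 0.50 without Enza_Ctrl replicate 2), KLK3 at -0.18 ± 0.63 (adjusted p = 0.870) and MKI67 at 0.43 ± 0.39 (adjusted p = 0.556). The signs of the last pair turned without Enza_Ctrl replicate 2, with KLK3 at 0.49 ± 0.47 and MKI67 at -0.08 ± 0.25 (adjusted p = 1.00 for both).

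By limma, 0 genes were called in LNCaPabl-Enza with 12 arrays, with 700 genes at an unadjusted p under 0.05 where 884 would be expected by chance. Without Enza_Ctrl replicate 2 the count was again 0, with 530 genes at an unadjusted p under 0.05. SGK1 was then at 4.43 ± 0.70 (SE), with an adjusted p of 0.269. Adjusted over the list alone, SGK1 passed among the glucocorticoid-induced genes with 12 arrays (adjusted p = 0.00157), and TMPRSS2 passed among the androgen-induced genes (adjusted p = 0.0443). Without Enza_Dex replicate 3, SGK1 was called as the only gene, at 3.43 ± 0.33 (SE) with an adjusted p of 0.0194.

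Camera called 9 lists in LNCaPabl-Enza with 12 arrays, and 0 with an estimated correlation, where the smallest adjusted p was 0.304. Glucocorticoid-induced genes were higher (20 of 28 positive, camera adjusted p = 0.0243; adjusted p = 0.304 with an estimated correlation). The epithelial sodium transport list was also higher (9 of 11 positive, camera adjusted p = 0.00873; adjusted p = 0.304 with an estimated correlation), as were androgen-induced genes (19 of 23 positive, camera adjusted p = 0.0116; adjusted p = 0.480 with an estimated correlation). These 3 lists were also called without Enza_Ctrl replicate 2 (camera adjusted p from 3.62e-05 to 0.000130; adjusted p from 0.0607 to 0.212 with an estimated correlation). They depended on other arrays: without Enza_Ctrl replicate 3 none of the 3 was called (camera adjusted p = 0.148, 0.0756 and 0.104), without Enza_Ctrl replicate 1 the glucocorticoid (0.0916) and androgen (0.0653) calls ended, and without Enza_Dex replicate 3 the androgen call did (0.112). With the dimmest genes left out, the glucocorticoid (0.0771) and androgen (0.0869) lists were not called.

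Other lists in LNCaPabl-Enza moved with the doubtful array. DNA replication genes were higher with 12 arrays (camera adjusted p = 0.0116; adjusted p = 0.670 with an estimated correlation; median 0.53) and had the opposite direction without it (adjusted p = 0.157). Unfolded protein response and fatty acid synthesis genes were higher (camera adjusted p = 0.0159 and 0.0243; adjusted p = 0.570 for both with an estimated correlation) and neuroendocrine markers lower (0.0116; adjusted p = 0.480 with an estimated correlation), and in the same fit without the array these lists were not called (adjusted p = 0.272, 0.192 and 0.0680). Cholesterol synthesis genes were higher and mesenchymal genes lower with and without it (camera adjusted p = 0.0116 and 0.00359 with 12 arrays, 0.0416 and 0.0423 without; adjusted p = 0.570 and 0.484 with an estimated correlation and 12 arrays, 0.523 and 0.212 without). Leaving it out moved their medians from 0.39 to 0.13 and from -0.43 to -0.08. Immune (13 of 15), endothelial (7 of 10) and fibroblast (9 of 15) markers also had mostly negative differences with 12 arrays and housekeeping genes positive ones (11 of 12), with no call by camera (adjusted p from 0.0606 to 0.190). The cholesterol call ended without Enza_Ctrl replicate 3 (adjusted p = 0.110) or Enza_Dex replicate 2 (adjusted p = 0.116). Cell division genes had 26 of 30 positive differences with 12 arrays (median 0.30, camera adjusted p = 0.0822) and turned to 28 of 30 negative without the doubtful array (median -0.16). Without it camera called them lower, metallothioneins higher and endothelial markers lower (camera adjusted p = 0.00268, 0.00889 and 0.0231; adjusted p = 0.523, 0.523 and 0.212 with an estimated correlation). After quantile normalization anew with 12 arrays, 2 of the 31 lists were called, epithelial sodium transport and androgen-induced genes, and the glucocorticoid-induced list had an adjusted p of 0.0775.

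The difference between the responses of the lines was tested directly. SCNN1G had the smallest p, with a response lower in LNCaPabl-Enza by -2.46 ± 0.41 on the log2 scale (SE, adjusted p = 0.793), or -2.50 ± 0.38 without Enza_Ctrl replicate 2 (adjusted p = 0.168). KLK4 was at -3.18 ± 0.71 (SE) and SGK1 at -2.84 ± 1.03. NR3C1 was at 0.72 ± 1.25, TSC22D3 at -0.95 ± 0.74, KLK3 at -1.94 ± 0.89 and MKI67 at 0.96 ± 0.56 (adjusted p = 0.832 for NR3C1 and 0.793 for the others). Leaving out Enza_Ctrl replicate 2 moved NR3C1 to 0.39 ± 1.12, TSC22D3 to -1.12 ± 0.67, KLK3 to -1.28 ± 0.63 and MKI67 to 0.45 ± 0.33 (adjusted p = 0.999 for each).

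By limma, 0 genes were called for this difference with 12 arrays (266 at an unadjusted p under 0.05) and 0 without Enza_Ctrl replicate 2 (566 at an unadjusted p under 0.05). KLK4 passed when adjusted over the list alone among the androgen-induced genes with 12 arrays (adjusted p = 0.0209) and SCNN1G in the sodium transport list (adjusted p = 0.000902). The untreated lines already differed in KLK4, a value looked up after the responses were seen, with 5.82 ± 0.65 in Abi_Ctrl and 8.03 ± 0.88 in Enza_Ctrl (SD, n = 3). That difference was 2.21 ± 0.50 (SE, limma adjusted p = 0.135), or 2.51 ± 0.46 without Enza_Ctrl replicate 2 (adjusted p = 0.0118). It uses the same DMSO arrays as the difference between the responses, with opposite sign, so the KLK4 results are not independent. Among the 25 genes called in LNCaPabl-Abi without the doubtful array, all 25 had a positive difference in LNCaPabl-Enza, and all 25 were smaller there. Their median log2 difference was 1.97 in LNCaPabl-Abi and 0.69 in LNCaPabl-Enza, and 21 of them passed the test of the difference when adjusted over the list alone. These genes were chosen for their size in LNCaPabl-Abi on the same arrays, so that count is not independent evidence and is biased towards a smaller response in the other line. Across all 17687 genes, which are not independent replicates, the log2 differences of the 2 lines had a Pearson r of 0.06 and a Spearman rho of 0.02, or 0.21 and 0.14 without the array.

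**Figure D3:**
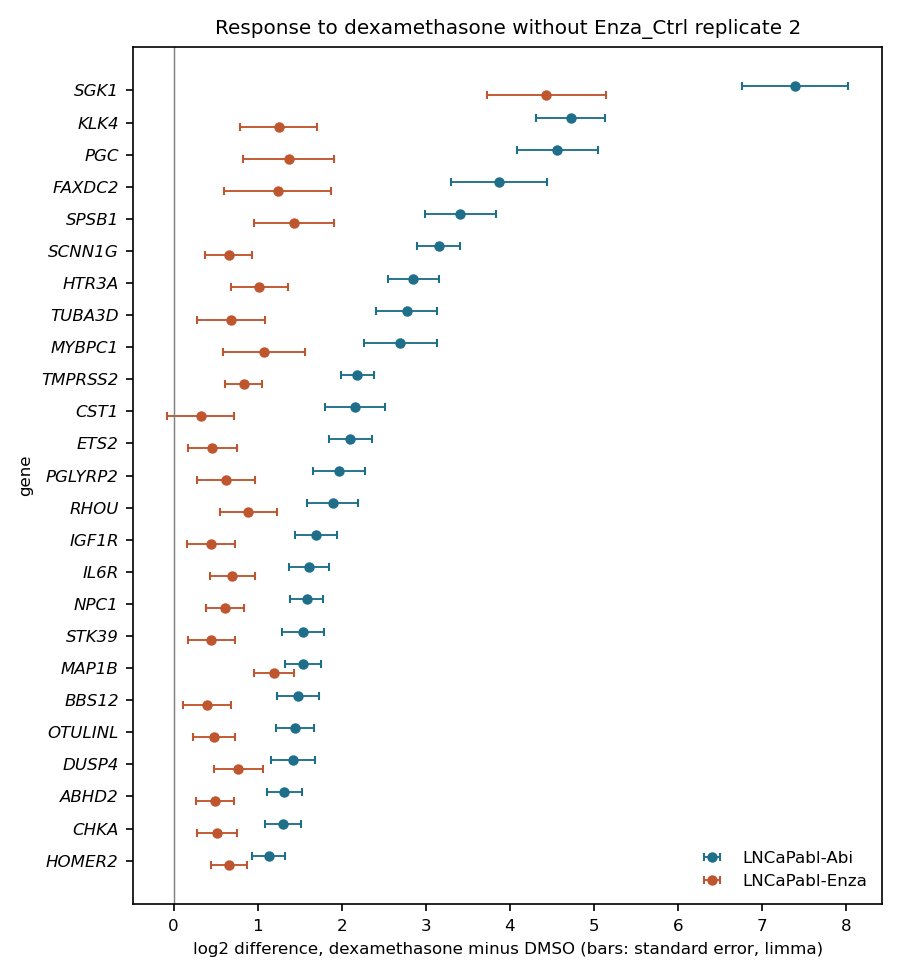
Log2 difference between dexamethasone and DMSO (x axis; bars are limma's standard errors) in both lines for the 25 genes called in LNCaPabl-Abi without Enza_Ctrl replicate 2, from 11 arrays. All 25 lie further right in LNCaPabl-Abi, the line they were chosen in, from SGK1 at 7.39 against 4.43 to HOMER2 at 1.13 against 0.66.

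Camera called 3 lists for the difference between the responses with 12 arrays. Cell division genes (median 0.85, camera adjusted p = 1.50e-08; adjusted p = 0.650 with an estimated correlation) and DNA replication genes (median 0.85, camera adjusted p = 7.45e-06; adjusted p = 0.759 with an estimated correlation) had a higher difference in LNCaPabl-Enza. Mesenchymal genes had a lower one (median -0.57, camera adjusted p = 0.000606; adjusted p = 0.578 with an estimated correlation), a call that ended after quantile normalization anew (adjusted p = 0.113). Neuroendocrine (13 of 16), endothelial (8 of 10), fibroblast (11 of 15) and immune (9 of 15) markers also had mostly negative differences and housekeeping genes positive ones (11 of 12), with no call by camera (adjusted p from 0.0540 to 0.279). The medians of the cell division, DNA replication and mesenchymal lists without Enza_Ctrl replicate 2 were 0.30, 0.22 and -0.23. Glucocorticoid-induced and epithelial sodium transport genes were then lower in LNCaPabl-Enza as lists (camera adjusted p = 0.0231 and 0.0176; adjusted p = 0.2498 for both with an estimated correlation). Also called only then were fatty acid oxidation and PPAR targets, higher in LNCaPabl-Enza (camera adjusted p = 0.0250; adjusted p = 0.2498 with an estimated correlation), and the unfolded protein response, lower (camera adjusted p = 0.0458; adjusted p = 0.706 with an estimated correlation).

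The untreated lines differed in 47 genes by limma with 12 arrays, 10 higher and 37 lower in LNCaPabl-Enza, and in 13 higher and 24 lower after quantile normalization anew. S100A10, a binding partner of annexin A2, was at 13.26 ± 0.78 in Abi_Ctrl and 7.11 ± 1.30 in Enza_Ctrl (SD, n = 3), a log2 difference of -6.16 ± 0.70 (SE, adjusted p = 0.00373). EFNA5, an ephrin ligand, was lower by -5.25 ± 0.58 (SE), CHN1, a GTPase-activating protein that turns Rac off, by -5.37 ± 0.78 and SDC2, a cell-surface heparan sulfate proteoglycan, by -5.18 ± 0.89. The RNA-binding splicing regulator MBNL2 was at -3.79 ± 0.28 (adjusted p = 0.000427), and SCRN1, GPX8, TLL1, MKX and ARID5B lay between -3.88 and -3.16.

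MMP16, a membrane-bound matrix metalloproteinase, was the gene with the highest difference, at 4.81 ± 0.33 in Abi_Ctrl and 9.79 ± 1.10 in Enza_Ctrl (SD, n = 3), a difference of 4.98 ± 0.52 (SE, adjusted p = 0.00213). TMSB10, an actin-sequestering thymosin, was higher by 4.09 ± 0.60 (SE), ATP1B1, a subunit of the sodium-potassium pump, by 3.17 ± 0.29 and the lipid flippase ATP11A by 2.58 ± 0.23. UGT2B17, UGT2B10 and UGT2B28 encode enzymes that attach glucuronic acid to steroids and other molecules. They were higher by 3.54 ± 0.56, 2.85 ± 0.44 and 2.01 ± 0.33 (SE), with adjusted p from 0.0290 to 0.0332. UGT2B15 was at 3.16 ± 0.57 (adjusted p = 0.0541). These paralogs are close in sequence, so a probe can respond to more than 1 of them, and UGT2B15 and UGT2B17 are uncertain as separate results. ADGRG6 and PLD1 were higher by 1.85 ± 0.32 and 1.93 ± 0.26. TSC22D3, KLK3 and MKI67 differed by 0.22 ± 0.53, 0.64 ± 0.63 and -0.56 ± 0.39, with adjusted p of 0.809, 0.544 and 0.451. Without Enza_Ctrl replicate 2 they differed by 0.39 ± 0.50, -0.02 ± 0.47 and -0.05 ± 0.25.

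The untreated lines differed in 228 genes without Enza_Ctrl replicate 2, 59 higher and 169 lower in LNCaPabl-Enza, which included all 47. Among those added were SI at 4.64 ± 0.67 (SE), UGT2B15 at 3.18 ± 0.55, ELOVL7 at 3.16 ± 0.60 and IFT57 at 3.05 ± 0.25, and, lower in LNCaPabl-Enza, IGFBP3 at -4.87 ± 0.94 and DAB1 at -3.61 ± 0.80. The count also moved with other arrays, from 11 without Abi_Ctrl replicate 1 upwards, and was 0 when only the 6 DMSO arrays entered the fit. With the 5 remaining DMSO arrays alone it was 117.

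Cholesterol synthesis genes were higher in untreated LNCaPabl-Enza as a list (camera adjusted p = 1.37e-05; adjusted p = 0.709 with an estimated correlation). Of 19 measured members, 16 had a positive difference, 0 were called over all genes and 6 passed when adjusted over the list alone, with INSIG1 at 1.26 ± 0.23 (SE), FDPS at 1.36 ± 0.28 and HMGCS1 at 1.00 ± 0.21. The call ended without Enza_Ctrl replicate 1 (adjusted p = 0.0630). Without Enza_Ctrl replicate 2, all 19 were positive with a median of 0.83, 6 were called and 14 passed when adjusted over the list alone (camera adjusted p = 7.58e-17; adjusted p = 0.160 with an estimated correlation). Mesenchymal genes were higher with 12 arrays (15 of 17 positive, camera adjusted p = 0.00317; adjusted p = 0.709 with an estimated correlation), a call that ended without the array (adjusted p = 0.0612) and after quantile normalization anew (adjusted p = 0.174). Immune (12 of 15), endothelial (8 of 10), fibroblast (10 of 15) and neuroendocrine (11 of 16) markers also had mostly positive differences with 12 arrays and housekeeping genes negative ones (11 of 12), with no call by camera (adjusted p from 0.0893 to 0.295).

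Fatty acid synthesis genes were higher in untreated LNCaPabl-Enza without Enza_Ctrl replicate 2 (12 of 16 positive, camera adjusted p = 1.52e-05; adjusted p = 0.209 with an estimated correlation). FASN, the fatty acid synthase, was then at 1.25 ± 0.22 (SE), ACSS2, which makes acetyl-CoA from acetate, at 1.34 ± 0.30 and the elongase ELOVL7 at 3.16 ± 0.60, and these were the 3 members called over all genes. Adjusted over the list alone, 0 members passed with 12 arrays and 6 without it. Androgen-repressed genes were higher as a list without that array (9 of 13 positive, camera adjusted p = 0.000369, and adjusted p = 0.209 with an estimated correlation). Its members include UGT2B15, UGT2B17 and UGT2B28. A probe can respond to more than 1 of these paralogs, so they may not count as separate members. ACKR3, a chemokine receptor on the same list, was lower at -1.14 ± 0.21 (SE). Cell division genes had 20 of 30 negative differences with 12 arrays (median -0.23, camera adjusted p = 0.746) and turned to higher without the array (27 of 30 positive, median 0.30, camera adjusted p = 4.22e-05, and adjusted p = 0.563 with an estimated correlation), with 0 members called. The response of LNCaPabl-Enza without the array (28 of 30 negative) uses the same Enza_Ctrl arrays with opposite sign. The cell division results are therefore not independent.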

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

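The tests on spike-ins were chosen after the array had been seen, as was the use of genes high in LNCaPabl-Enza, and the test for an array of the other line with genes high in LNCaPabl-Abi was written before its result. Gene lists whose dexamethasone response differed between the lines, by the test of the difference itself, were cell division (camera adjusted p = 1.499e-08, 30 of 30 members higher in LNCaPabl-Enza), DNA replication (adjusted p = 7.45e-06, 29 of 30 higher) and mesenchymal genes (adjusted p = 0.000606, 16 of 17 lower). With an estimated correlation the adjusted p were 0.650, 0.759 and 0.578, and with fry 0.654, 0.783 and 0.654. The mesenchymal call ended after quantile normalization anew. Without Enza_Ctrl replicate 2 the camera adjusted p were 5.04e-06, 0.0176 and 0.0492. The medians then shrank from 0.85, 0.85 and -0.57 to 0.30, 0.22 and -0.23. The response of cell division genes within LNCaPabl-Enza turned from 26 of 30 positive to 28 of 30 negative.

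Rows without a gene symbol here, which take no part in the comparisons of genes, also differed between the untreated lines. When each of 24257 rows was tested alone, 44 were called, of which 6 had no symbol. Without Enza_Ctrl replicate 2 these counts were 147 and 19.

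Enza_Ctrl replicate 2 stood apart from the other 11 arrays, and no biological explanation was tested because the design gives it the same group as 2 other arrays. An array of the other line under this label cannot be told apart: 19 genes higher in LNCaPabl-Abi by at least 2 on the log2 scale had a median position of 0.0245 (95% bootstrap interval -0.193 to 0.203; 0 is the Enza and 1 the Abi level), within the limit of 0.25 set before, but lost signal (upper quartile 8.74 against 9.96 to 10.1) lowers such genes in either line, and 13 genes higher in LNCaPabl-Enza had 0.125 (0.0198 to 0.766). Degraded cell RNA alone is argued against by the poly-A spike-ins, which are added to the RNA and lay 3.61 below the lowest of the other arrays, whose whole range was 1.03. A loss of labelled target before hybridization is a candidate explanation, since the spike-ins averaged only 3.46 while the hybridization controls, added after labelling, averaged 13.94, above the highest of the others at 11.43. No test separates it from other causes that lower the spike-ins, so the explanation stays open.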

How the results depend on the processing

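Fits without Enza_Ctrl replicate 2 that add a block or use fewer groups were chosen after seeing the data. Genes called in LNCaPabl-Abi numbered 22 with only the groups compared (21 higher, 1 lower), 37 with array weights (34 higher, 3 lower; all 25 among them) and 39 with a replicate block and without Enza_Ctrl replicate 2. Leaving out each array gave 0 to 25 genes: 2 without Abi_Ctrl 1 or Abi_Dex 2, 0 without Abi_Ctrl 2, 3 without Abi_Ctrl 3, Abi_Dex 1 or Enza_Dex 2, and 25 without Enza_Ctrl 2. In LNCaPabl-Enza the range was 0 to 1, the 1 being SGK1 without Enza_Dex 3, where its adjusted p was 0.0194, against 0.0769 to 1.00 in the other settings. The difference between responses had 0 genes under each omission of 1 array and 1, SCNN1G at -2.36 ± 0.28 (SE), with the block and without Enza_Ctrl 2. The untreated lines differed in 0 genes with only the groups compared, 252 with array weights, 303 with the block and 117 with only DMSO arrays, the last pair without Enza_Ctrl 2, and in 11 to 228 over omissions, with 11 without Abi_Ctrl 1, 99 without Enza_Ctrl 3 and 228 without Enza_Ctrl 2. The cause was not tested beyond the residual spread, 0.43 with and 0.26 without Enza_Ctrl 2.

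Arrays with the same replicate number shared some variation, with deviations that correlated at 0.14, 0.08 and 0.30 in LNCaPabl-Abi and at 0.01, 0.00 and 0.08 in LNCaPabl-Enza (0.06 and 0.22 for replicates 1 and 3 without Enza_Ctrl 2). Not every pair was over 0.1 and the labels give the numbers no meaning. The main fit did not treat the arrays as paired. The block tried as an alternative gives a replicate number the same effect in both lines, so pairing within a line was not tested. Of 12 arrays, 8 correlated best with their own number among the 3 arrays of the other treatment, a hint from the data and not from the design. The replicate block with 12 arrays called 4, 0, 0 and 64 genes in the 4 comparisons, and the Abi gene it did not call was PGC (adjusted p = 0.117). In the same order, the lists called went from 9, 9, 3 and 2 to 3, 0, 0 and 0 with an estimated correlation and to 3, 3, 0 and 0 with fry. In LNCaPabl-Enza 2 were called after quantile normalization and 2 without the dimmest genes. For the difference between responses 7 were called without the dimmest genes, 7 with array weights and 6 with the block and without Enza_Ctrl 2. For the untreated lines the counts were 4 with only the groups compared, 4 with the block, 5 with array weights, 5 with the block and 6 with DMSO arrays alone, the last pair without Enza_Ctrl 2. Omissions gave 6 to 12, 4 to 11, 3 to 8 and 1 to 6 lists. DNA replication in LNCaPabl-Enza turned from higher to lower with array weights (adjusted p = 0.194) and without Enza_Ctrl 2 (0.157; 0.644 with the block; 0.114 with Enza arrays alone), and over omissions its adjusted p ran from 0.000982, without Enza_Ctrl 3, to 0.157. Without Enza_Ctrl 2, other fits changed list calls in LNCaPabl-Enza: the block called the unfolded protein response (0.0318), and neither the block nor Enza arrays alone called cholesterol synthesis (0.146 and 0.0569) or mesenchymal genes (0.0631 and 0.0980). The Pearson r between the responses was 0.183 with array weights, 0.254 with the block and without Enza_Ctrl 2, and 0.00875 to 0.205 over omissions.

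Of the called values of named genes, 0 reversed. Among uncalled values the sign turned under some alternative for 10 genes in LNCaPabl-Enza, 2 between the untreated lines and 1 for the difference between responses. Other splits of the arrays: 1 of 10 splits, the real one, called 5 genes in LNCaPabl-Abi (highest other 0), 1 of 10 called 47 between the untreated lines (highest other 0), and 10 of 10 called 0 in LNCaPabl-Enza. With 10 splits no share under 0.05 can be reached. For the difference between responses, 100 of 100 splits drawn called at least the real 0, which a count of 0 makes certain, so this says nothing about chance. The highest other, 5, exchanged the treatments in LNCaPabl-Enza alone and so tested the sum of the responses. Signal near the background probes (2.77 to 2.92 on 11 arrays) limits what can be measured for dim genes.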

Other observations

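The tests of an offset, of NR3C1, of the share of mixed cells and of the excess they would give were chosen after the arrays had been seen, and the test of the position between the lines was written before its result. Interferon response genes were lower in untreated LNCaPabl-Enza without Enza_Ctrl replicate 2 (12 of 20 negative, camera adjusted p = 0.0316, and adjusted p = 0.209 with an estimated correlation), and metallothioneins too (8 of 9 negative, camera adjusted p = 0.0239, and adjusted p = 0.686 with an estimated correlation). The metallothionein rise after dexamethasone in LNCaPabl-Enza uses the same Enza_Ctrl arrays with opposite sign, so it is not independent of this result. Of the interferon genes, OAS1 was at -1.08 ± 0.25 (SE, limma adjusted p = 0.0496) and IFIT1 at -1.15 ± 0.28 (adjusted p = 0.0695). PPARGC1A, a coactivator of mitochondrial genes, was at -2.23 ± 0.47 (adjusted p = 0.0306).

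Replicate 3 differed from the other arrays of its line for several genes that separate the untreated lines, with and without dexamethasone. UGT2B17 was at 12.50 and 12.35 on the Abi arrays of replicate 3 and between 10.39 and 11.19 on the other Abi arrays. IGFBP3 was at 11.03 and 10.75 there and between 12.60 and 13.68 on the others. In LNCaPabl-Enza, CHN1 was at 9.87 and 9.30 in replicate 3 and between 6.75 and 7.48 otherwise, and SI was at 9.42 and 8.88 and between 6.32 and 6.94 otherwise. TMSB10, higher in LNCaPabl-Enza, was at 7.83 and 7.998 in replicate 3 and between 9.52 and 9.88 on the Enza arrays of the other replicates. In Enza replicate 3, CHN1 and TMSB10 thus lay towards the Abi level and SI away from it. In Abi replicate 3, UGT2B17 and IGFBP3 lay towards the Enza level. These genes are examples, and the share of all genes that differ in this way was not counted.

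Of the 25 genes called in LNCaPabl-Abi without Enza_Ctrl replicate 2, 23 were highest in replicate 3 among the Enza_Dex arrays, where 36.3% of all genes were, and their median excess of 0.64 lay above that of all 10000 random lists matched on expression (highest 0.34), while the 28 glucocorticoid-induced genes had a median excess of 0.11, at percentile 91.9 of such lists. An offset without dexamethasone is argued against, because the ratio of the genes' median excess with DMSO to that with dexamethasone was -0.317 (95% bootstrap interval -1.05 to -0.0501), although this sets 1 DMSO array against 1 and the interval covers genes, not arrays (in 7 other pairs of arrays of 1 group these genes had a median difference of at most 0.17). Cells of the Abi line mixed into replicate 3 cannot be told apart from other causes by the position test, which gave 0.316 (0.181 to 0.447, 18 genes) between its limits of 0.25 and 0.5. NR3C1 was left out of those genes after its value had been seen. On the deposited scale, the highest share of Abi cells that those genes allow had a median of 14.6% (95% bootstrap interval over genes 10.0 to 24.0). It ran from 1.20% for S100A10 to 86.2% for LRRTM1, and NR3C1 would need 54.1%. A share of 24.0% would leave a median excess of 0.215 (0.109 to 0.385), and a share of 1.20% would give a median excess of only 0.03. On that scale the median share argues against mixing at the NR3C1 share, and the excess left argues against mixing as the whole cause. A step that widens contrast would make the shares too small, so neither is excluded and mixing stays open. More receptor mRNA is a candidate explanation, since NR3C1 was higher in both replicate 3 arrays than in each other Enza array by at least 1.60, but it rests on 2 arrays that also differ in other genes.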
